A study of Mus with 6 samples.

How the data were processed

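RNA was sequenced from pancreatic tumors grown in genetically obese and in lean mice, with 3 libraries in each group. Per the labels' protocols, total RNA was extracted with a phenol reagent (QIAzol), purified with a kit, and depleted of ribosomal RNA before library construction, so transcripts without a poly(A) tail and unspliced RNA can also be counted. The authors deposited 1 table of raw counts per gene for the 6 libraries. Per the submitters' processing notes, CASAVA, STAR and Subread were used with the mouse build GRCm38; their versions, settings and strand handling are not given in the sources used here. The deposited table lists 15646 genes by versioned Ensembl ID, and the lowest sum over the 6 libraries is 11, so scarce genes had been removed by a rule not given in the sources used here. Each of the 6 columns carried the title of 1 sample, and 0 columns were left unmapped.

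Libraries whose titles start with OB were taken as the obese group. The design text names 2 kinds of mice, so the other titles, which start with ND, were taken as the lean group. Libraries are named by the number in their title: obese 1, 3 and 4 and lean 1, 2 and 3. No label says which libraries came from separate mice, so the p-values measure the spread between these samples, which may in part be technical. No label names a batch, a sequencing date or a litter.

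Gene symbols could not be attached. The RefSeq gene table used here, of the assembly GRCm38.p6, has 49997 rows, of which 0 carry an Ensembl ID, and 0 of the 15646 IDs were matched. Genes are therefore given by ID, at most 2 per direction. Before the data were examined, 56 lists of genes had been fixed by symbol (nerve, Schwann cell, adipocyte, acinar, islet, fibroblast, immune, metabolic and other lists); none could be looked up, and the planned list tests were not run. The planned rule for named genes took, in each direction, called genes with a mean of at least 1 CPM (counts scaled to the size of the library) and no overlap between the groups, in order of fold change, 12 per direction. It also took list members and some genes chosen by symbol whatever their values. Only the order could be applied: its condition on symbols was dropped, 1424 higher and 1486 lower genes passed, and the first 2 of each direction were named. Strand handling being unknown, reads of overlapping or antisense genes, and of near-identical copies, cannot be told apart for these IDs.

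The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter at its default settings (minimum count 10, minimum total 15), which left 14348 genes and removed 1298. Libraries were scaled by TMM factors, and the groups were compared with the quasi-likelihood F test, two-sided, without covariates. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested are called changed. The standard error (SE) of a log2 fold change was computed as its size divided by the square root of F. Log2 CPM values for the principal components and correlations used a prior count of 2. For a gene with 0 counts in a group, the fold is a lower bound against a floor of 3 counts over that group; where a group held 1 to 3 counts, the ratio of summed counts per effective library size is given with an exact (Clopper-Pearson) 95% interval. Floors and intervals cover counting error only, and the lower bound takes the counts of the other group as exact. Single values per library were compared by an exact permutation test, two-sided, which cannot go below 0.1 with 3 against 3 libraries.

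The test was checked on counts simulated from the real means, dispersions and library sizes for 14348 genes, of which 200 were changed. In this simulation of the obese against lean comparison, the edgeR test recovered, of those left by the filter, 16.7% of 66 genes changed 1.5-fold, 62.1% of 66 changed 2-fold and 95.5% of 66 changed 4-fold, with 10 false calls among 125. With no gene changed, it made 4 calls over 14110 genes. The simulation changed fewer genes than the 2991 called in the data, which makes the adjusted threshold stricter. The recovered shares may therefore be lower than those of the real comparison.

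Alternatives fixed before the data were examined were RLE and upper-quartile factors, total counts only, no filter, a filter on a CPM of at least 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), a robust fit, the replicate number as a block, and leaving out each library. Added later were removal of the 10 most abundant genes, thinning of every library to the smallest total, and a test against a 1.5-fold change. Lists of cell-cycle genes keyed by Ensembl ID, taken from marker pairs in the scran 1.30.0 package, were also added later and tested with camera and fry.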

Results

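Total RNA was profiled in orthotopic pancreatic tumors, that is, tumors grown from cells placed in the pancreas itself. The cells, KPC1199, are a mouse pancreatic ductal adenocarcinoma line. The hosts were ob/ob mice, which lack functional leptin and become obese, or lean wild-type mice. The single comparison of the design, 3 tumor libraries from obese against 3 from lean mice, asks how the tumor transcriptome differs with obesity of the host. The libraries held between 7122533 counts (lean 2) and 8521244 counts (lean 1), with a mean of 7994945 ± 760884 (SD, n = 3) in the lean and 8171627 ± 334002 (SD, n = 3) in the obese group. Totals did not separate the groups (exact permutation test, p = 0.9). Of the 15646 listed genes, between 15461 and 15534 had at least 1 count in a library. A gene with 0 counts in a library could still be present at up to 0.352 to 0.426 CPM, the level of 3 counts.

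The tumors separated by host. The first principal component carried 54.1% of the variance of log2 CPM and placed the lean tumors between -46.0 and -25.6 and the obese tumors between 29.0 and 43.6 (exact permutation test, p = 0.1, the smallest that 3 against 3 allows). The second component carried 15.0% of the variance and set obese 3, at -37.7, apart from the other 5 libraries, which lay between -6.45 and 17.5. Over the genes tested, Pearson's r between 2 libraries was 0.972 to 0.981 in the 6 pairs within a group and 0.937 to 0.958 in the 9 pairs between groups. Within a group, the counts of a pair differed by 7.28 to 14.2 times the sampling variance per gene, so no pair looked like a library deposited more than once. The corresponding range between groups was 18.6 to 40.2.

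**Figure D1:**
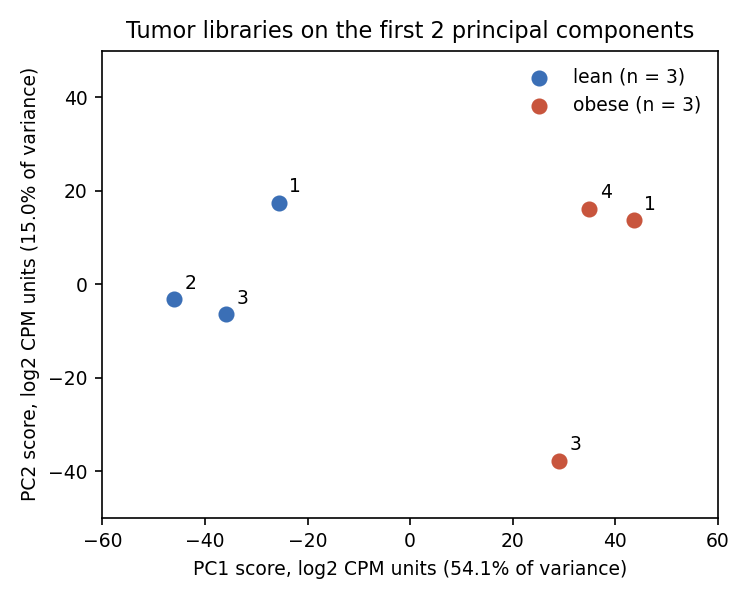
Scores of the 6 tumor libraries on the first and second principal components of log2 CPM (both axes in log2 CPM units, with the percent of variance), each point a library labelled with its replicate number. The lean libraries lie at -25.6 or lower on the first component and the obese libraries at 29.0 or higher, while obese 3 lies apart on the second.

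Expression of 2991 of the 14348 genes tested differed between tumors of obese and lean mice (20.8%; edgeR quasi-likelihood test, adjusted p under 0.05). The changes were balanced: 1474 genes were higher and 1517 were lower in obese hosts. Most were moderate, with a median fold of 1.70 among the genes that rose (log2 0.76, interquartile range 0.55 to 1.14) and of 1.62 among those that fell (log2 -0.70, interquartile range -1.10 to -0.50). At least 2-fold changes were fitted for 482 of the genes that rose and 451 of those that fell, and at least 4-fold changes for 93 and 81. When the test itself was made against a change of 1.5-fold, 213 genes passed, 95 of them higher and 118 lower. The typical SE of a log2 fold change was 0.19 (median over genes), and the common biological coefficient of variation was 16.4%. At an unadjusted p under 0.05, 5188 genes would have been counted.

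The libraries of the groups did not overlap for 2907 genes that were higher and 2874 that were lower in every obese library, together 40.3% of the genes tested, where chance alone gives 10%. Of the 2991 called genes, 2922 showed no overlap and 69 did. The count differed with the libraries included: it was 1179 without lean 2, 1461 without obese 1, 1541 without lean 3 and 1956 without obese 4, whereas without lean 1 or obese 3 it was 2624 or 3066. The balance of directions depended on scaling. With TMM factors 49.3% of the called genes were higher in obese hosts, and with total counts only this was 60.6% (1797 higher and 1170 lower).

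**Figure D2:**
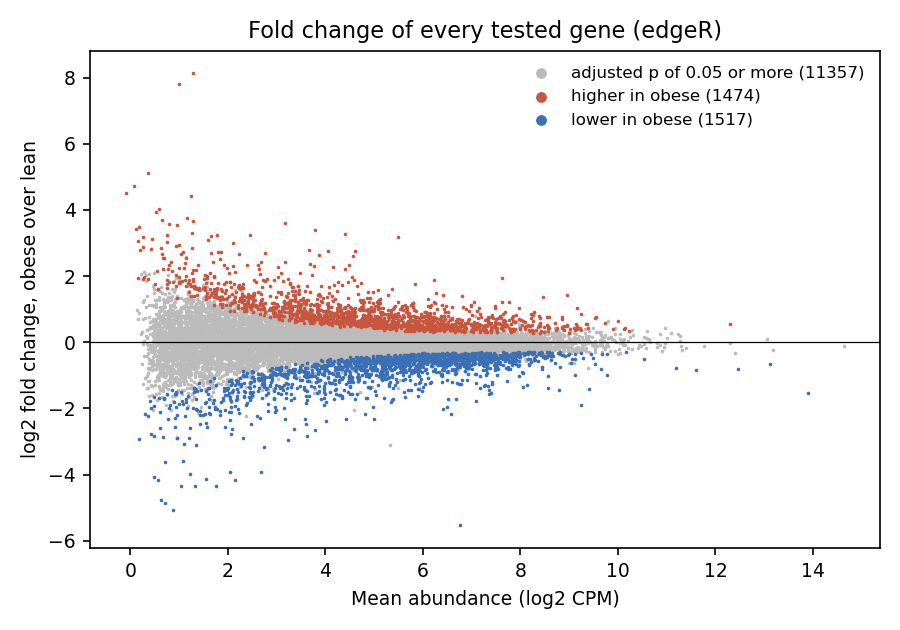
Log2 fold change, obese over lean, against mean abundance in log2 CPM for each of the 14348 genes tested. Red and blue points are the 1474 higher and 1517 lower genes at an adjusted p under 0.05, grey points the rest, and the spread of the unchanged genes widens toward low abundance.

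The genes with the greatest fold changes and no overlap between groups were scarce transcripts that were close to absent from one kind of tumor. ENSMUSG00000076614.7 had 32 to 39 counts in each obese library, or 4.32 ± 0.353 CPM (SD, n = 3), and 0 counts in each lean library, so that it was at least 33.8-fold higher in obese hosts (edgeR adjusted p = 0.00133). ENSMUSG00000030546.14 had 25 to 33 counts in each obese library, 3.45 ± 0.556 CPM (SD, n = 3), against 0 in each lean library, at least 26.9-fold higher (edgeR adjusted p = 0.00201). The lean group's floor for both was 0.128 CPM, the level of 3 counts over its 3 libraries.

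In the other direction, ENSMUSG00000117231.1 fell from 3.17 ± 0.344 CPM in lean to 0.0793 ± 0.0687 CPM in obese hosts (SD, n = 3 each; edgeR adjusted p = 0.00193). Its 74 counts in lean against 2 in obese libraries gave a ratio of 39.4 with a 95% counting interval of 10.5 to 332. ENSMUSG00000058914.12 fell from 2.80 ± 1.27 to 0.0816 ± 0.141 CPM (SD, n = 3 each; edgeR adjusted p = 0.00457), with 64 counts in lean and 2 in obese libraries, a ratio of 34.1 (95% counting interval 9.06 to 288). The 2 obese counts of this gene were in obese 3. Its fitted log2 fold change was -4.87 with all libraries, -7.49 without obese 3 and -3.96 with the replicate block. The intervals are wide because the obese libraries together held only 2 counts of each of these genes. Each of the named genes had at most 39 counts in any library.

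**Figure D3:**
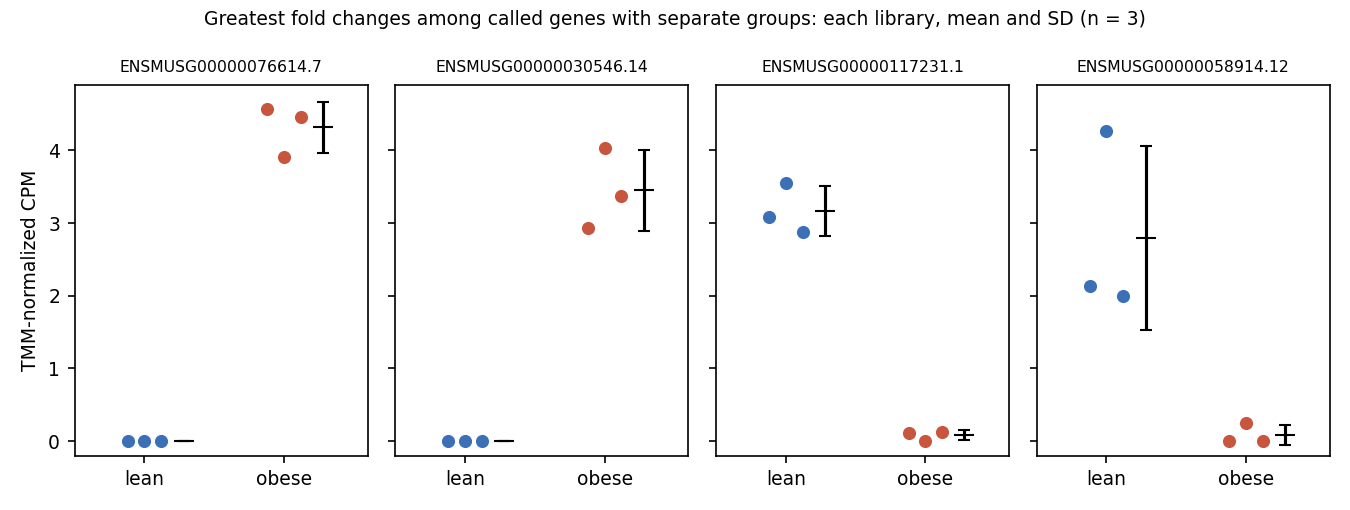
TMM-normalized CPM of the 4 genes named by the fixed order, 1 panel per gene ID, with each library as a point and the mean and SD beside it (n = 3 per group). The first and second genes are at 0 in the 3 lean libraries and at 2.93 CPM or more in the 3 obese ones, and the other 2 genes are at 0.245 CPM or less in the 3 obese libraries, below each lean one.

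Of the 10 most abundant genes, 3 were lower and 1 was higher in obese hosts, and 6 did not pass the test. The 10 most abundant genes took 10.2% ± 0.963 of the counts in lean and 8.12% ± 0.332 in obese tumors (SD, n = 3 each; exact permutation test, p = 0.1, the smallest possible). The most abundant gene did not pass the test, at 26323 ± 3389 CPM in lean and 24476 ± 2613 CPM in obese tumors (SD, n = 3 each; edgeR adjusted p = 0.627). The second most abundant gene fell from 22810 ± 4074 to 7859 ± 2707 CPM (SD, n = 3 each), a log2 fold change of -1.54 with an SE of 0.22 (edgeR adjusted p = 0.00277). The fourth and sixth in abundance fell as well, with log2 fold changes of -0.67 (SE 0.15, edgeR adjusted p = 0.0118) and -0.80 (SE 0.13, edgeR adjusted p = 0.0041). The eighth rose by 0.55 on the log2 scale (SE 0.14, edgeR adjusted p = 0.0214).

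Calls were unevenly spread over abundance. In the fifth of genes with the lowest mean abundance, up to 4.93 CPM, 178 genes rose and 144 fell, so 11.2% were called. In the fifth with the highest, above 83.0 CPM, 306 rose and 474 fell, so 27.2% were called. Higher expression in obese hosts thus made up 55.3% of the calls among the scarcest genes and 39.2% among the most abundant, a difference of 16.0 percentage points (95% interval 9.63 to 22.5). It was 5.47 points without obese 3 (-1.12 to 12.1) and 7.23 without lean 2 (-3.83 to 18.3), intervals that include 0. With total counts only it was 7.58 points (1.23 to 13.9). These intervals treat the called genes as independent and leave out the spread between libraries. They therefore cannot show whether the difference belongs to the host.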

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

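The count of changed genes stayed within 1.5 times the 2991 of the edgeR test under every planned choice of scaling, filter and test. Apart from the replicate block, it ranged from 2903 without a filter to 3099 with DESeq2 (limma-voom 3006), and 2834 and 2873 of the genes of those extremes were also among the 2991, in the same direction. It was 2987 without the 10 most abundant genes and 2907 with every library thinned to the smallest total, alternatives chosen after seeing the data. The test against a 1.5-fold change, also chosen then, left 213. Leaving out 1 library gave 1179 to 3066 changed genes, 567 to 1468 higher, 612 to 1598 lower, and 505 to 1112 changed at least 2-fold; the direction was kept in each case for every gene also called with all 6 libraries. The count fell in 5 of these and rose without obese 3, so fewer libraries alone did not set it; the cause was not tested. Only the numbers 1 and 3 occur in both groups, and their libraries' deviations from the group means correlated at 0.090 and 0.074. Pairs with unlike numbers ranged from -0.131 to 0.066. The like-numbered pairs were thus the highest, though by little, and whether a number pairs the samples cannot be told. With the replicate block, 2087 genes were called, 1777 of them among the 2991. The 4 named genes kept direction and threshold in all 17 alternatives each, with adjusted p-values of 3.48e-07 to 0.0283. The alternatives that drop genes of other tissues, and all list tests, were not run, since the lists are by symbol. The filter on CPM kept 14673 genes and so was looser, not stricter, than the main one. Depth limits what a count of 0 excludes, to 0.352 to 0.426 CPM per library; whether it set the share called by abundance was not tested.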

Other observations

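The cell-cycle lists and their tests, the thinning, the removal of the 10 most abundant genes, the use of total counts to weigh abundant genes, the pattern of calls over abundance and the counts of genes present in 1 group were chosen after the main results were seen.

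Genes that mark the G2 and M phases of the cell cycle were on balance higher in obese hosts, with a call that did not hold in every test. The lists came from marker pairs for mouse cells keyed by Ensembl ID, each reduced to genes listed as high in 1 phase alone. Of the 28 G2/M genes tested, 7 rose, 1 fell and 20 did not pass the threshold over all genes tested; adjusted over the list alone, 10 rose and 1 fell. Their median log2 fold change was 0.37, and camera with its preset correlation gave an adjusted p = 0.0142 over the 3 lists. The adjusted p = 0.372 with an estimated correlation, and fry's directional test gave an adjusted p = 0.0255, for whether the genes moved on balance in 1 direction. The mean log2 CPM of the list was 4.94 to 5.09 in the lean and 5.25 to 5.33 in the obese libraries. Of the 35 S-phase genes, 5 rose and 3 fell (camera adjusted p = 0.658), and of the 11 G1 genes, 4 rose and 1 fell (camera adjusted p = 0.551), with a median log2 fold change of -0.07 and a mean of 0.04 that differ in sign. Whether the G2/M list changed more than the others was not tested.

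A candidate explanation for the G2/M call is that its members vary together between libraries, so that fewer of them count as independent. Their estimated correlation was 0.063, and with it the call was lost (camera adjusted p = 0.372), which this explanation would give. Whether a few abundant genes matter cannot be told apart by their removal (adjusted p = 0.0141 without the 10 most abundant), because this moved almost no value. The call also ended without lean 3 (median 0.26, camera adjusted p = 0.056). A difference in proliferation between hosts stays open and untested.

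For the number of changed genes, the tables argue against a difference in depth, because 2907 genes were called with every library thinned to the same total, and against a few abundant genes as the whole cause. TMM factors moved the median log2 fold change of all genes from 0.07 with total counts only to 0.01, and 2644 genes were called in the same direction with both. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 2991 genes, and the highest of the other splits gave 0 (edgeR). So few splits cannot give a share under 0.05. Each other split also put libraries of both hosts on each side, so a strong group difference of any cause lowers its calls. The 0 is therefore no measure of what chance gives. GC content and gene length cannot be told apart from the host effect, as 0 gene IDs had a value for either. The host genotype and weight, and any shared handling of a group that the labels do not record, stay open. No test here separated tumor cells from other cells in the samples, since the alternatives that drop genes of other tissues were not run. The calls therefore do not show in which cells expression differed.

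The tilt of calls with abundance, higher among scarce and lower among abundant genes, may rest on single libraries rather than on the host. It was 16.8 percentage points between the fifth with the lowest and that with the highest abundance after thinning, which argues against a difference in depth. Removal of the 10 most abundant genes (15.3 points) moved too little to decide on their part. Per library, the median deviation of scarce minus abundant genes was 0.24 in obese 3 and between -0.06 and 0.04 in the other 5 libraries, so it did not separate the groups (exact permutation test, p = 0.2). With total counts only the tilt was 7.58 points, so its size depends on scaling. No biological explanation was tested for it.

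Of all genes in the table, 2, the named ENSMUSG00000076614.7 and ENSMUSG00000030546.14, had at least 10 counts in each obese library and 0 in each lean one, 0 genes had the opposite pattern, and the 9 other splits gave 0 such genes in either direction. The gene with the lowest fitted fold change among those called (log2 -5.53, SE 1.31, edgeR adjusted p = 0.0161) is not among the named ones because its groups overlap: it had 36, 4029 and 495 counts in lean 1, 2 and 3, and 25, 55 and 34 in obese 1, 3 and 4.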
